A study of Mus musculus with 6 samples.

How the data were processed

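ATAC-seq peaks of 1 library were analysed, that of untreated E14 NSD1-dTAG mouse embryonic stem cells in 2i/LIF medium. The labels list 6 samples, 1 in each of 6 groups. Groups were taken from the sample titles, because the treatment labels of the 1 h and 24 h samples both state 6 h. Per the labels' protocols, isolated nuclei were treated with Tn5, and the libraries were amplified by PCR and selected for size. The submitters' processing notes name bcl2fastq 2.20.0.422, Bowtie2 2.3.4.1, SAMtools 1.9, MACS2 2.2.6, deepTools 3.2.1 and the builds GRCm38.p6 and mm10. Filters on mapping quality, duplicates and mitochondrial reads, and any shift of reads for the Tn5 insertion site, are not given in the sources used here. Reads from repeated sequence, if kept, would raise peaks there. The peaks were called on this 1 sample, per the labels.

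The deposited peak list gives an integer score per peak, which was the authors' -log10 q times 10 in 100% of peaks, rounded down. Its fold enrichment is the authors' ratio of summit pileup to local background. The authors' -log10 p and -log10 q stand in 2 further columns, and the lowest deposited -log10 q was 1.3, that of a q of 0.05. The file's label names no control, so the local background came from the same library. The list gives positions from 0, printed here from 1. No intervals overlapped, and each held 1 summit.

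The total read count was not given in the sources used here. The depth at each summit was recovered from 2 relations, fold = (pileup + 1)/(background + 1) and the Poisson probability of exceeding the pileup given the background, solved together. Whole pileups resulted for 77626 of 77629 peaks (99.996%, tolerance 0.01), the exceptions being the 3 mitochondrial peaks. The genome-wide background of 1.3 applied to 23044 peaks (29.7%). Whether a unit of pileup is a read or a fragment is not given in the sources used here. Intervals of pileups are exact Poisson intervals, and cover counting error only. PCR copies, if kept, are not independent molecules.

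Genes came from a RefSeq table of GRCm38.p6, the build named in the notes, which holds gene coordinates, biotypes and symbols but no strand, transcript starts or exons. The planned promoter windows were therefore replaced by windows of 1 kb either side of both annotated ends of 21887 protein-coding genes, and exon and intron shares gave way to gene bodies. A peak counted as at a gene end if it overlapped a window by 1 bp or more, and as distal otherwise. An internal start of a gene is thus distal. Planned matching of random lists on promoter CpG content was replaced by 5 bins of gene length crossed with 5 bins of neighbouring protein-coding gene ends within 50 kb. The 20 motif consensus sequences fixed for distal summits were not searched, since no genome sequence was used here. Density per Mb used the span from the first to the last annotated gene of a chromosome, within which peaks were also placed at random 100 times with their widths kept.

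The 22 gene lists, the rule for named genes and part of the alternative settings were fixed before the data were examined, and the other alternatives were chosen after seeing the data. Named genes were 14 fixed ones, for each list the 2 members with the highest fold at a gene end and the first 2 in alphabetical order without a peak, the 5 core and naive genes with the most distal peaks, and the 10 distal peaks with the highest fold on chromosomes 1 to 19 and X. Ties in distal peaks were named together. The result of 1 gene that this rule selects is not reported here. Other genes in the text, such as further members without a peak, were named after their values were seen. Shares carry Wilson 95% intervals, their difference a Newcombe interval, and differences of medians bootstrap intervals (500 draws of peaks, 10000 draws of genes). With 1 library no p-value was computed. Percentiles among 10000 random lists describe this library and treat no gene as a replicate. No list shared a gene with another.

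The functions were tested on simulated data. All of 5000 simulated pileups were recovered exactly, and all of 2000 genes with a planted peak among 8000 random peaks were found. Of 200 simulated lists of 20 genes with peaks in 90% of genes against a background of 60%, 87.0% exceeded the upper limit of the central 95% of random lists, as did 1.0% of 200 unchanged lists. Alternatives varied the q threshold, the windows, the overlap rule, the radius, the measure of strength, the random lists and the tallest and widest peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with a fixed seed.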

Results

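Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in E14 mouse embryonic stem cells. The cells carried an NSD1-dTAG knock-in, a fusion that lets the small molecule dTAG-13 direct the NSD1 protein to degradation. NSD1 is a methyltransferase for lysine 36 of histone H3, and the series addresses its part in enhancer regulation and cell fate. The labels describe 6 samples in 6 groups of 1: cells in 2i/LIF medium at 0, 1, 6 and 24 h of 500 nM dTAG-13, and embryoid bodies at day 6 with and without dTAG-13. Peaks of the untreated 0 h library were analysed here, and the other 5 samples were not analysed here, so no effect of NSD1 loss was measured. There are no replicates, and the intervals below cover counting error or the spread over genes or peaks within this library, not the spread between libraries.

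The untreated library held 77629 peaks, of which 77533 lay on chromosomes 1 to 19, X and Y. They covered 45.2 Mb, with a median width of 487 bp and a median fold enrichment of 7.05 (range 1.32 to 39.73). Fold enrichment is the authors' own value for each peak and is used only to describe and rank peaks within this list. The summit pileup, the number of reads or fragments stacked at the summit, had a median of 23 and quartiles of 14 and 45. At the genome-wide background of 1.3 the lowest listed pileup was 6, so sites with a pileup of 5 or fewer were not detectable there.

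Accessible sites were concentrated at the ends of protein-coding genes, and the sites there were the taller and wider ones. Of the peaks on chromosomes, 15776 (20.3%, Wilson 95% interval 20.1 to 20.6) lay within 1 kb of an annotated gene end, against 3.95% of randomly placed peaks (range 3.83 to 4.16 over 100 placements). Gene bodies away from the ends held 39.3% of peaks, close to the 38.0% of random placement, and sequence outside protein-coding genes held 40.3% against 58.0%. The median fold enrichment was 9.87 at gene ends and 6.52 at distal sites, a ratio of 1.51 (bootstrap 95% interval 1.49 to 1.53). By summit pileup the medians were 54 and 20, a ratio of 2.70, and by -log10 q the ratio was 3.09. Gene ends made up 59.9% of the tenth of peaks with the highest pileup and 5.77% of the tenth with the lowest. The gene table gave no strand, so start and end of a gene could not be separated. Among 17675 genes longer than 4 kb, 60.4% had a peak at 1 end alone, 13.3% at both and 26.4% at neither.

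Most core and naive pluripotency genes and most genes of the 3 germ layers had accessible ends, but the pluripotency genes had the taller peaks. Of 40 core and naive pluripotency genes, 36 (90%, Wilson 76.9 to 96.0) had a gene-end peak, as did 55 of 64 neurectoderm, mesoderm and definitive endoderm genes (85.9%, 75.4 to 92.4). The difference of 4.06 percentage points (Newcombe 95% interval -10.5 to 16.2) was not detectable at these list sizes. It was 12.5 points when a pileup of at least 20 was required, a value inside that interval. The median pileup of those peaks was 105.5 at the core and naive genes and 36 at the germ-layer genes, a difference of 69.5 (bootstrap 95% interval 35 to 84). Among 10000 random lists of genes with a peak, matched on gene length and local gene density, these medians stood at percentiles 100 and 0.18. The naive genes alone had a median pileup of 115.5, at percentile 99.98. The core genes alone had one of 82.5, at percentile 96.7, inside the central 95% of random lists. Median fold enrichment set the groups less apart, at 7.13 and 6.43. Both lay below the median of 11.1 over all protein-coding genes with a gene-end peak, and no percentile was computed for fold. For each gene, fold and pileup below are those of its gene-end peak with the highest fold, and the genes said to lead a list have its highest folds. With peaks in gene bodies counted as well, 39 of 40 core and naive genes and 61 of 64 germ-layer genes had one. A gene without a gene-end peak can thus have a peak inside.

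All 20 core pluripotency genes had a gene-end peak. Pou5f1, which encodes the transcription factor OCT4, had a pileup of 152 (Poisson 95% interval 129 to 178) and a fold of 5.86 at chromosome 17, 35503733 to 35505356. That peak's summit lay beyond the 1 kb window. With the summit required in the window, or with windows of 500 bp, the pileup of Pou5f1 was 55. Sox2 had a pileup of 119 (98.6 to 142) and Nanog one of 58 (44.04 to 74.98). Zfp281 and Dppa2 had the highest folds of the list, 14.0 and 9.70. Of 20 naive genes, 16 had a gene-end peak. Klf5 (pileup 256, fold 13.3) and Stat3 (156, fold 14.5), a transducer of LIF signalling, led by fold, and Klf4 and Zfp42 had pileups of 114 and 134. Esrrb, Dppa3, Nr5a2 and Pecam1 had none at either end. Inside the body of Esrrb the tallest peak reached 179, at chromosome 12, 86501617 to 86502372.

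**Figure D1:**
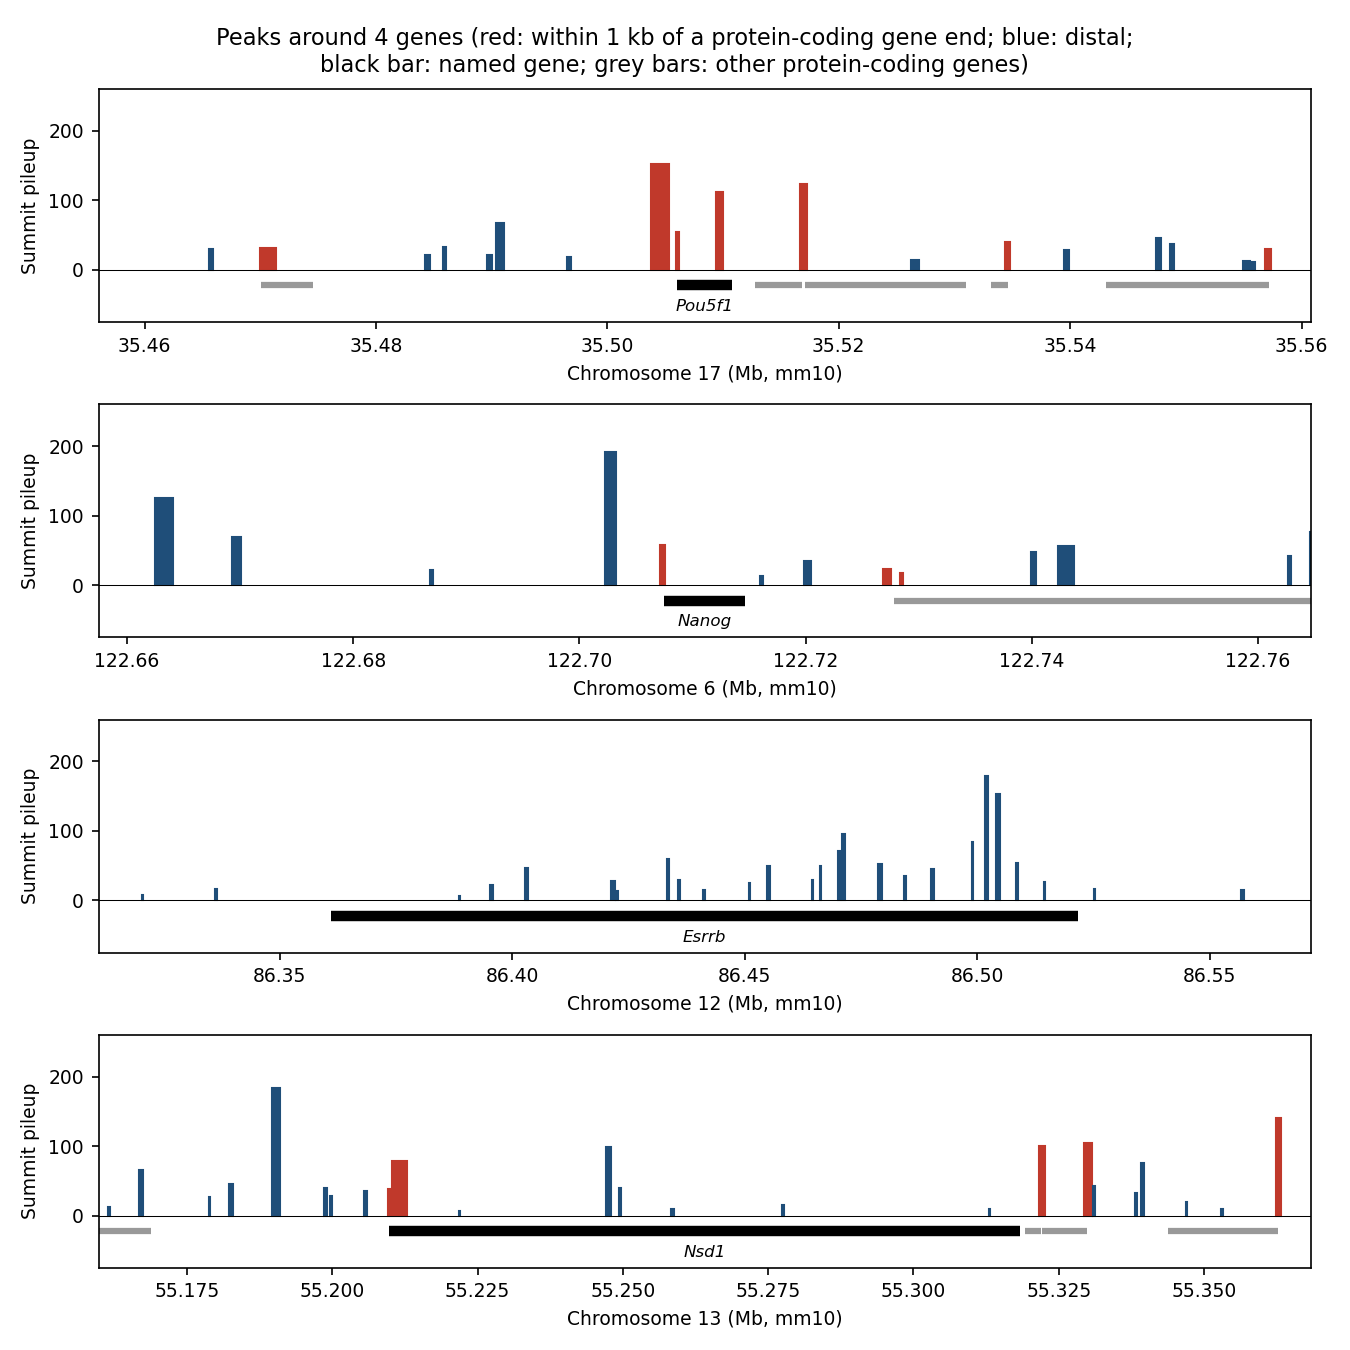
Peaks around Pou5f1, Nanog, Esrrb and Nsd1, from 50 kb below to 50 kb above each gene; the horizontal axis is the position in Mb (mm10), and bar height is the summit pileup. Esrrb has no red bar (a peak within 1 kb of a protein-coding gene end) and its tallest blue (distal) bar reaches 179, while the tallest bar near Nanog, 192, is distal.

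The germ-layer genes had low but widespread peaks. In neurectoderm, 21 of 22 genes had one, led by Tubb3 (fold 13.4, pileup 36) and Map2 (13.2, pileup 51), both of the neuronal cytoskeleton. Pax6 had a pileup of 15 (8.40 to 24.7), a peak lost at a -log10 q of at least 5. Inside the body of Pax6 the tallest peak reached 52. Six3 had no gene-end peak but one of 42 in its body. In mesoderm, 19 of 22 had a gene-end peak, led by fold by Isl1 (12.4, pileup 69) and Mixl1 (12.3, pileup 56). T, which encodes Brachyury, had a pileup of 25 (16.2 to 36.9), and Meox1, Myf5 and Tbx5 had none. In definitive endoderm, 15 of 20 had one, led by fold by Apoa1 (pileup 59) and Foxa3 (120). Sox17 had a pileup of 62 (47.5 to 79.5), but no gene-end peak with windows of 500 bp or with the summit required in the window. Without the 0.1% highest folds and 1% widest peaks, Sox2, Sox17, T and Nsd2 had no gene-end peak. Afp and Alb, the fetal and adult serum albumins, had none, nor did Cldn6, Foxa1 and Hnf4a.

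Of 20 formative and primed genes, 16 had a gene-end peak with a median pileup of 47. Tcf15 and Wnt8a led by fold, both at 10.3, with pileups of 75 and 68. Cer1, Dnmt3a, Lefty2 and Sall2 had none at their ends, though Dnmt3a had one of 41 in its body. In extraembryonic endoderm 13 of 18 genes had a gene-end peak (median pileup 48). Plat and Lrp2 had the highest folds, 14.0 and 13.1, and Gata6 had a pileup of 28 (18.6 to 40.5). Cubn and Dab2 had none at their ends but peaks of 65 and 35 in their bodies. With gene bodies counted as well, all 18 had a peak. In trophectoderm 11 of 18 had a gene-end peak (median pileup 42), led by Tead4 and Krt8, with none at the ends of Elf5 and Esx1.

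Genes of adult tissues and blood had fewer accessible ends than matched random lists. Of 20 adult tissue genes 5 had a gene-end peak (25%, Wilson 11.2 to 46.9), against a mean of 67.5% in matched random lists. The share was 15% when a pileup of at least 20 was required. Ckm and Scgb1a1 were among the 5, and the liver genes Cyp2e1 and Cyp3a11 were among the other 15. Blood genes had 9 of 20 (45.0%, 25.8 to 65.8, random mean 70.9%). Klf1, an erythroid regulator, had the highest fold at 14.7 and Epor followed at 9.28, while Cd8a had none. Both shares lay under the first percentile of their random lists, at 0.01 and 0.605. The random lists were matched on gene length and neighbouring gene ends, not on promoter CpG content. With gene bodies counted as well, 8 of 20 adult tissue genes and 13 of 20 blood genes had a peak. Median gene-end pileups were 20 for adult tissue genes and 25 for blood genes, at percentiles 1.17 and 0.26. Fibroblast and feeder genes had a gene-end peak in 12 of 20, at percentile 25.8, but with a median pileup of 30.5, at percentile 0.92. Snai2 and Cdkn2a led, and Acta2 and Col3a1 had no gene-end peak. Germline genes had 12 of 18, at percentile 35.6, but with a median pileup of 17, below that of every matched random list. With a pileup of at least 20 required, their share was 22.2%. Hormad1 (138) and Dazl (66) had the tallest peaks, and Asz1 and Piwil1 had none. A peak at a gene end can belong to a neighbouring gene, which the table could not resolve.

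Families expressed in specialised or early embryonic cells had the fewest accessible ends. Of 1106 olfactory receptor genes 20 had a gene-end peak (1.81%, Wilson 1.17 to 2.78), among them Olfr95 and Olfr94. That share was 0.452% when a pileup of at least 20 was required and 4.25% with windows of 2500 bp. Of 353 vomeronasal receptor genes 9 had one (2.55%, 1.35 to 4.77), led by Vmn2r29 and Vmn1r4, and with windows of 2500 bp the share was 4.53%. In the fixed list named for a rare 2-cell-like state of embryonic stem cell cultures, only Zfp809 of 13 had one, at a pileup of 89. Whether Zfp809 is particular to that state was not tested. Zscan4c, Zscan4d, Zscan4f, Tcstv1 and Spz1 were among the 12 without. Many of these genes have near-identical copies, so missing peaks there are uncertain.

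Genes used in every cell were accessible nearly throughout. All 30 ribosomal protein genes had a gene-end peak, with a median pileup of 93 and the highest folds at Rps3 and Rpl27. Of 22 housekeeping genes 20 had one (median pileup 84), led by Psmb2 and Emc7. Ywhaz had none at its ends but one of 151 in its body, and Hprt had none at its ends or in its body.

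All 25 Polycomb genes had a gene-end peak (median pileup 85), with the highest folds at Pcgf3 and Phc2. So did all 20 genes of enhancer cofactors and remodellers (median 85), led by Med13 and Smarca4. Hox genes, whose clusters are classic Polycomb targets, had a peak in 35 of 39 with a median pileup of 28, below every matched random list. Neighbouring Hox genes can share peaks, and the random lists drew scattered genes. The comparison thus treats clustered genes as separate, here and for distal peaks below. Hoxc13 reached 108, and Hoxa2, Hoxb3, Hoxd10 and Hoxd12 had none. Of 18 imprinted genes 13 had one (median 45), led by Plagl1 and the antisense transcript Kcnq1ot1, and H19, Igf2, Mest, Nnat and Snrpn had none. For the 4 imprinted genes that are not protein-coding, the windows lay at their own ends. A peak there can also count as distal, since distal was defined by protein-coding gene ends.

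**Figure D2:**
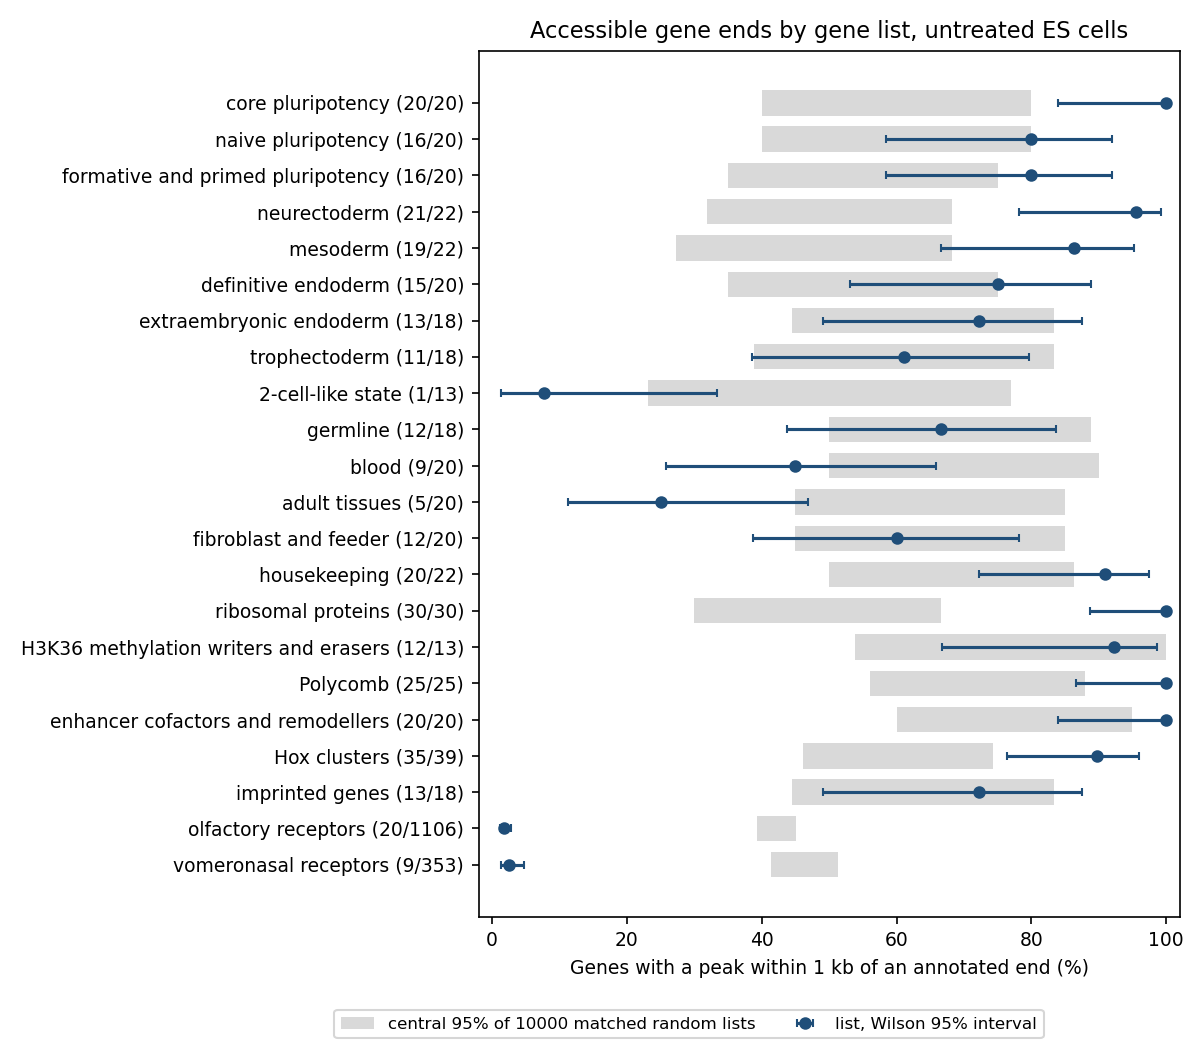
Share of genes in each of 22 lists with a peak within 1 kb of an annotated end (points, horizontal axis in percent, Wilson 95% intervals) beside the central 95% of 10000 matched random lists (grey bars). Core pluripotency, ribosomal protein, Polycomb and enhancer cofactor genes sit at 100%, and olfactory receptors at 1.81%.

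The genes of the H3K36 methylation machinery were accessible in 12 of 13 cases (92.3%, Wilson 66.7 to 98.6), with a median pileup of 87. Nsd1 itself, the tagged gene, had a gene-end peak at chromosome 13, 55210184 to 55212901, with a fold of 5.34 and a pileup of 78 (61.7 to 97.3). That peak's summit lay beyond the 1 kb window, and the peak with its summit inside had a pileup of 39. Within 50 kb of its ends Nsd1 had 19 distal peaks, the tallest at 183 (157 to 212) and 19.4 kb outside the gene. Nsd2 had a gene-end pileup of 42 (30.3 to 56.8) and 3 distal peaks, and Nsd3 one of 107 (87.7 to 129) and 6. Setd2, which trimethylates the same lysine, had 96 (77.8 to 117) and 9. Setmar had a fold of 16.2. Kdm4c had no peak at either end but one of 114 in its body.

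Distal accessible sites were denser around pluripotency genes than around germ-layer genes. The median number of distal peaks within 50 kb of either gene end was 10 for the core and naive genes and 5 for the germ-layer genes, a difference of 5 (bootstrap 95% interval 4 to 7). The difference was 2.0 within 20 kb and 8.5 within 100 kb. When only distal peaks with a pileup of at least 20 were counted, the medians were 7 and 3, a difference of 4. With every distal peak within 50 kb counted, the median over all protein-coding genes was 4. Matched random lists had medians of 3 for the first group and 2 for the second, and both groups stood at percentile 100. Against unmatched random lists the germ-layer median fell to percentile 85.3. Jarid2 had 21 distal peaks, Pecam1 and Tet1 had 18 each, and Trim71 had 17. Esrrb, Lifr, Nr5a2, Tet2 and Zfp42 had 15 each. The tallest near Nanog, at chromosome 6, 122702264 to 122703223, had a pileup of 192 and lay 4.77 kb outside the gene. Sox17, Map2 and Cer1 were among the genes with no distal peak in that radius, and Pax6, T and Gata6 had 9, 5 and 4.

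Among the other lists, Hox genes had a median of 9 distal peaks (random median 4), trophectoderm genes 8 (3.5), Polycomb genes 8 (5), enhancer cofactors 8 (6), ribosomal protein genes 7 (3) and H3K36 genes 7 (6). Formative and primed genes and housekeeping genes each had a median of 6.5, extraembryonic endoderm genes 6, and imprinted genes 4.5. Blood genes had 4, fibroblast and feeder genes 3.5, germline genes 3, adult tissue genes 2.5 and 2-cell-like genes 2. Both receptor families had a median of 1. Counting only distal peaks with a pileup of at least 20 lowered most of these medians by over 1.5 times, for example to 5 for Hox genes, 4 for Polycomb genes and 1 for germline genes.

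**Figure D3:**
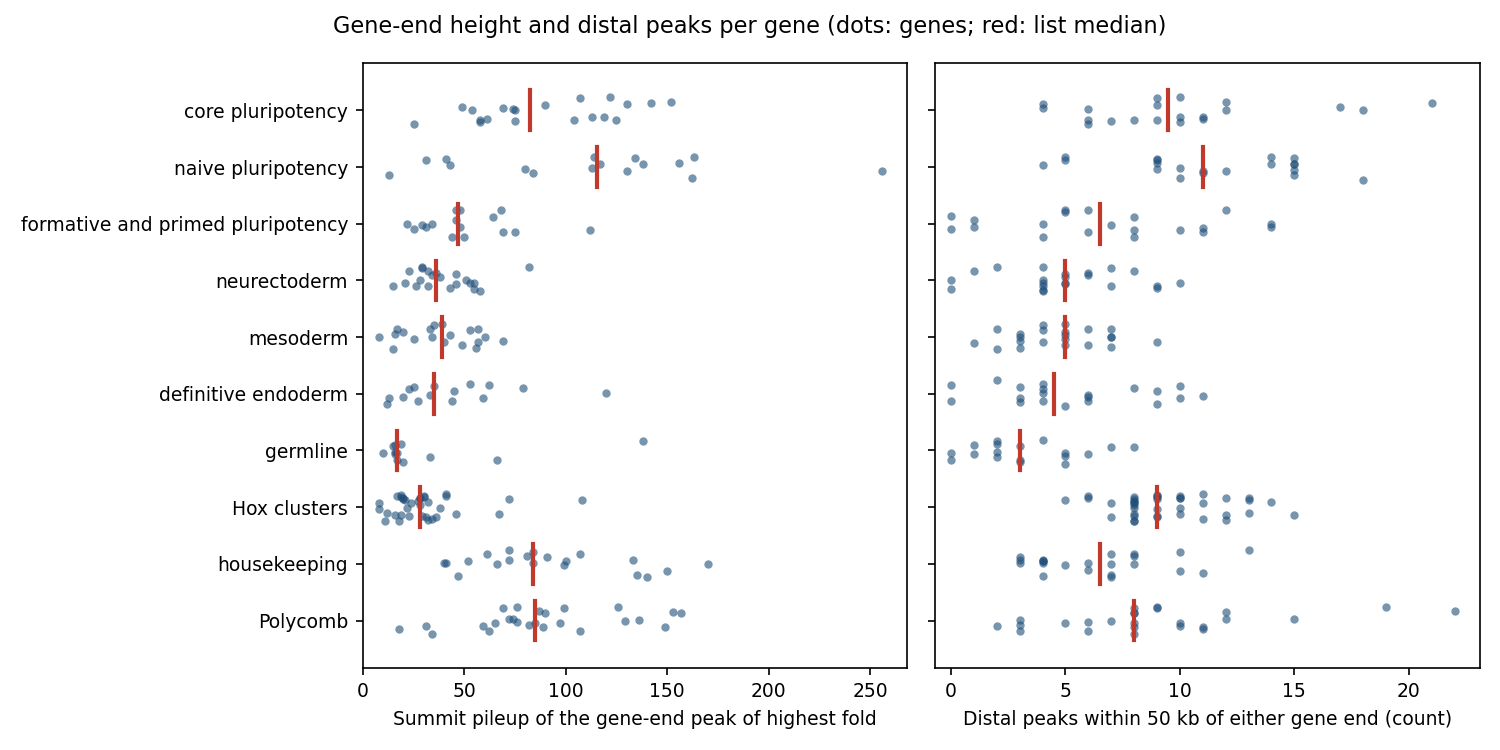
Summit pileup of each gene's gene-end peak of highest fold (left) and number of distal peaks within 50 kb of either gene end (right) for 10 lists, 1 dot per gene, with list medians as red lines. The naive list has a median pileup of 115.5 and the neurectoderm list one of 36, and distal medians run from 3 for germline genes to 11 for naive genes.

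The 10 distal peaks with the highest fold lay on 8 chromosomes. The highest, a fold of 39.73 and a pileup of 200, lay at chromosome 1, 100180112 to 100180374, inside a gene body and nearest to Gm29667. The next lay near Myl12b (fold 38.6), Rpusd4 (38.4), Gphn (37.2), Chl1 (37.1), Adgre5 (36.5), Lama1 (35.6), Il31ra (35.2), Camk1d (34.9) and Vmn1r204 (34.8). Of these 10 peaks, 8 were under 500 bp wide, against a median of 432 bp over all distal peaks.

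The X chromosome had fewer peaks per Mb and lower gene-end pileups than any autosome. It had 12.9 peaks per Mb (exact Poisson 95% interval 12.3 to 13.4), against an autosome median of 31.2 that ranged from 23.6 on chromosome 14 to 43.5 on chromosome 11, a ratio of 0.412. Protein-coding genes were also sparser on X, at 5.66 per Mb against 7.85. A gene-end peak was present at 47.6% of X genes, against an autosome median of 69.5%. The 90th percentile of gene-end pileup was 79.0 on X and between 128 and 152 on the 19 autosomes. Median fold at gene ends differed less, at 9.49 on X and 9.95 as the autosome median. At distal sites the median pileup was 18 on X against 20, and the median fold, 7.21, was above that of every autosome (highest 6.95).

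**Figure D4:**
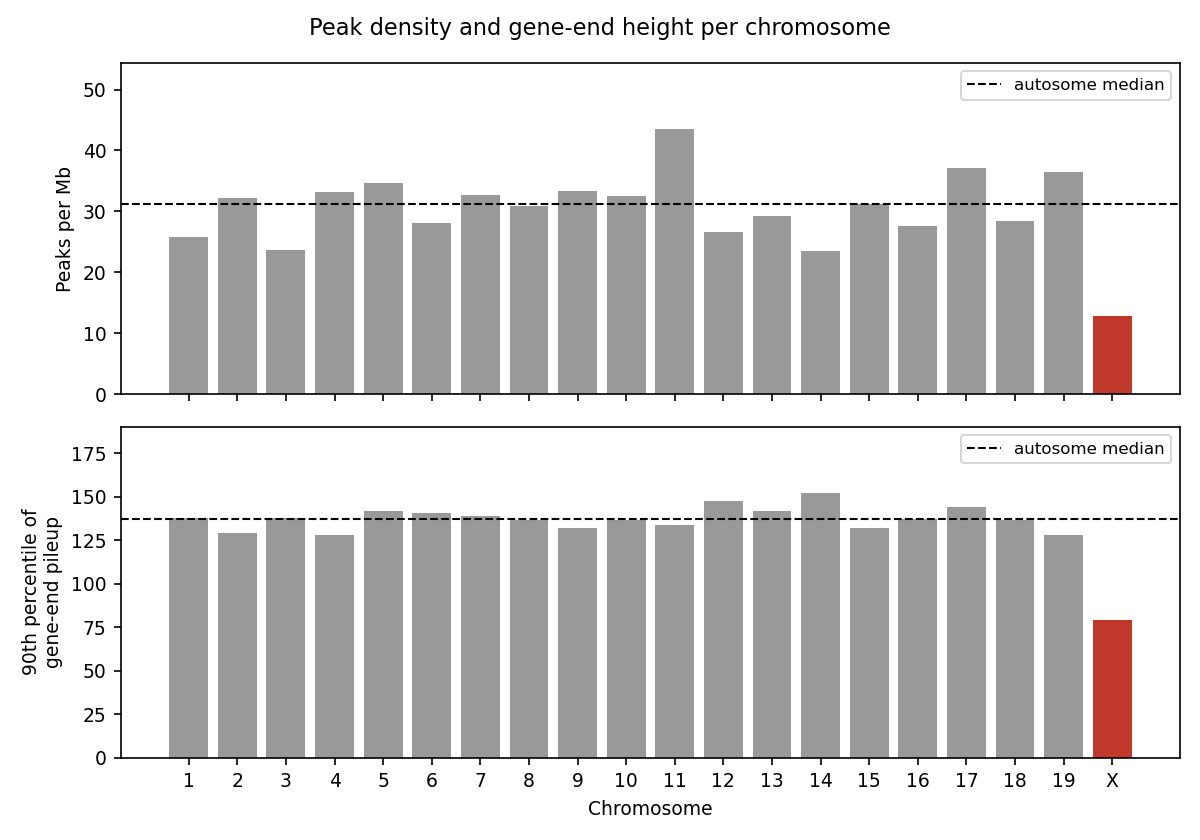
Peaks per Mb (top) and the 90th percentile over genes of gene-end summit pileup (bottom) for each autosome (grey) and X (red), with the autosome median as a dashed line. X is the lowest in both panels, at 12.9 peaks per Mb and a pileup of 79.0.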

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

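The tests in this part were chosen only after the results were seen, except that the bounds for peak width were written before widths by list were computed, though after the pattern itself was seen. No biological explanation was tested, since 1 group was analysed.

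Outside the chromosomes used in the report, 93 peaks lay on 28 unplaced scaffolds. Their median pileup was 16, but scaffold JH584304.1 held 19 peaks and the highest pileup, 2294. The mitochondrial genome held 3 peaks with pileups from 3451 to 3614, rounded values because the recovery gave no whole pileup for them.

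X had fewer peaks per Mb and lower gene-end pileups than every autosome. The 4 autosomes closest to X in gene density (5.66 to 6.17 genes per Mb, against 5.66 on X) had 23.7 to 28.5 peaks per Mb, and X at 12.9 (12.3 to 13.4) had 0.543 of the lowest, which argues against fewer genes as the whole source. Per gene the gap was less clear, since X had 0.590 (0.565 to 0.615) of the autosome median and gene-dense chromosome 7 had 0.606. A single copy of X, as in a male line such as E14 is known to be, would lower pileups on X: the 90th percentile was 0.576 of the autosome median at gene ends (single autosomes 0.934 to 1.11) but 0.864 at distal sites, so that explanation stays open. Autosomal peaks thinned at random to 50% of their pileup stayed above the lowest listed -log10 p in 82.1% of cases, against a density ratio of 41.2%. Thinning as simulated thus left part of the lower density unexplained. A simulation excludes nothing, so a single copy stays open for the density too.

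Narrow towers stood among the tallest distal peaks. Of 424 distal peaks with a pileup of at least 150, 13.7% (58, Wilson 10.7 to 17.3) were under 500 bp wide, against 0.260% (2 of 768, 0.0714 to 0.944) at gene ends. Gene-end peaks were wider at all heights together, with a median of 819 bp, so this comparison does not decide whether the narrow class is made of ordinary accessible elements. Copies collapsed in the reference may be another source, and 36 distal peaks against 2 gene-end peaks had a pileup of at least 400. That count does not decide either, because no sequence was searched.

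Core and naive pluripotency genes stood out by high pileup, but not by high fold. Their median fold was 7.13, below the median of 11.1 over all protein-coding genes with a gene-end peak. No percentile was computed for fold. The local background at the core and naive genes was 13.2. That is 1.99 times that of gene-end peaks of the same pileup (mean of random medians 6.63, central range 5.75 to 7.70). Since fold is the ratio of pileup to background, this restates the lower fold at these genes and explains nothing. Their peaks were wider, 1101 bp against 957 bp, a ratio of 1.15 that lay between the bounds, so whether wide peaks raised their own background stays open. At germ-layer genes the ratio of widths was larger, 1.31, and that of backgrounds smaller, 1.52.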

How the results depend on the processing

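The share of peaks at gene ends stayed between 17.6% and 26.8%, the gene-end to distal ratio of medians above 1.3, the distal difference above 0 and the X density ratio below 0.6 under each alternative run. Alternatives using all biotypes, pileup or counts per gene or per 100 kb were chosen after seeing the data. The share at gene ends was 17.6% with windows of 500 bp, 26.4% with 2500 bp, 18.6% with the summit in the window, 23.0% at a -log10 q of at least 5, 19.9% without the 0.1% highest folds and 1% widest peaks, and 26.8% with ends of every biotype. In the same order the strength ratio was 1.61, 1.32, 1.56, 1.35, 1.53 and 1.39; it was 3.09 by -log10 q and 2.70 by pileup. The distal difference was 2.0 at a radius of 20 kb and 8.5 at 100 kb. The X ratio was 0.335 for peaks with a pileup of at least 40 and 0.590 per protein-coding gene (autosomes 0.606 to 1.27). Windows, radii and thresholds act by construction; otherwise the cause was not tested. The pluripotency minus germ-layer share ran from 3.75 to 12.5 percentage points, within its main interval throughout. Per list, 13 of 192 shares (7 higher, 6 lower) and 69 of 264 distal medians (25 higher, 44 lower) left their intervals, as did 4 of 84 named pileups, all lower. Further named peaks were lost: Nsd2, Sox2, Sox17 and T without the highest and widest peaks, Sox17 also with 500 bp or the summit in the window, and Pax6 at a -log10 q of at least 5. Against unmatched lists the germ-layer distal median stood at percentile 85.3. Collapsing overlaps moved nothing, since none overlapped. The motif search, its alternatives and 1 start per gene were not run. No paired analysis was possible because 1 library was analysed. Depth limits the list at a pileup of 6 or more over the genome-wide background.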

Other observations

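Non-coding genes differed widely in accessibility, and the comparisons in this part were chosen after seeing the data. Of 408 tRNA genes 286 (70.1%, Wilson 65.5 to 74.3) had a peak within 1 kb of an end, against 7.55% under random placement, with a median pileup of 74. Away from protein-coding gene ends the share was 66.3% (238 of 359). Long non-coding RNA genes had 35.8% (random 14.1%), and 25.8% of the 9861 away from coding gene ends. MicroRNA genes had 25.5% (random 7.53%), and 19.1% of the 1078 away from coding gene ends. Pseudogenes, at 10.6% against 10.2%, and immunoglobulin and T-cell receptor V segments, at 7.11% against 7.92%, lay near random placement.

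Grouped by the letters that open their symbols, families of at least 20 protein-coding genes ran from no accessible end to accessible ends in every member. None of 21 Lce genes of the cornified skin layer, 24 Mup genes of the major urinary proteins or 26 Prl genes of the prolactin family had a gene-end peak. The Krtap family of hair keratin-associated proteins had 2 of 56 and the Defb family of beta-defensins 3 of 42. All 28 Polr genes (median pileup 88.5), 29 Mrps genes (78), 26 Cdk genes (84) and 24 Taf genes (70) had one. The Zfp family of zinc finger proteins had 359 of 397 (90.4%). The tallest gene-end peaks were at Lars2 (pileup 938, only 390 bp wide), Gm40469 (424) and Wls (396, only 273 bp wide). Zfp960, Desi2 and Smarca5 followed at 319, 299 and 285. The peaks at Lars2 and Wls were under 500 bp wide, like the narrow towers above, whose source stays open. Among protein-coding genes of up to 100 kb, Sptbn4 had the most distal peaks within 50 kb of its ends (29), followed by Bcat1 (27).

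Hprt, on X at 52988078 to 53021660, lay in an interval of 88.2 kb without a peak, from 52962294 to 53050445. Of 22 housekeeping genes it alone had no peak at its ends or in its body. Some E14 sublines are known to have lost Hprt function, and which subline was used is not given in the sources used here. Peaks on X numbered 12.9 per Mb, a mean spacing not far below 88.2 kb, so the gap alone does not show a loss of Hprt. The tallest peak of the list, with a pileup of 5947, lay on chromosome 2 at 98666245 to 98667311, outside gene ends. It was 1067 bp wide, so it was not among the narrow towers, and whether repeated sequence raised it was not tested.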
